A study of Mus musculus with 6 samples.

How the data were processed

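RNA sequencing of selected mRNA was carried out, per the labels' protocols, on mouse bone marrow-derived macrophages, which are primary macrophages grown from bone marrow cells with the growth factor M-CSF (20 ng/ml). All 6 libraries came from wild-type cells stimulated with R848 (100 ng/ml) for 6 h. R848, or resiquimod, is a small-molecule agonist of the endosomal receptors TLR7 and TLR8. Before stimulation, 3 samples had received DMSO, a common solvent for such compounds, and 3 an inhibitor of the lysine acetyltransferase KAT8. The labels used here name neither the compound nor its dose nor the length of pretreatment.

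The authors deposited a single table of raw read counts per Ensembl gene, with 1 column for each library and no normalization. Per the submitters' processing notes, HISAT2, StringTie 1.3.0 and edgeR were used with the mouse genome build mm10. The role of each tool, the read counter, the annotation release, the treatment of reads that match several places and whether strand was used in counting are not given in the sources used here. Counts of genes with near-identical copies, such as ribosomal protein genes and Gapdh, and of overlapping genes therefore depend on rules that are not known. Besides the overlaps given with the results, exons of Ccna2, Eln, Fcgr2b, Il4ra and Psmb8 overlap genes on the opposite strand. Gene coordinates are those of the GENCODE annotation of the same build, matched by Ensembl identifier and counted from 1.

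The table listed 34745 genes, of which 478 had no symbol. These held 0.143% to 0.199% of the counts of a library and were kept in the totals and tests. In all 6 libraries 14936 genes were at 0. Library totals ranged from 18441352 to 25089320 counts. A count of 0 in a library allowed a level of up to 0.12 to 0.163 CPM, the usual unit of counts scaled to library size, taking 3 counts as the limit. Such limits cover counting error only, because reads without molecular identifiers are not independent molecules.

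Samples were grouped by their titles, which give the pretreatment and a replicate number. The labels do not say that replicates came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. Replicates were compared before averaging. Within a group, the chi-square statistic per degree of freedom of paired counts was 9.91 to 15.4, so no library was a copy of another. Between groups it was 93.9 to 113.

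Differential expression was tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16, with TMM scaling, the filterByExpr filter (which takes a minimum count of 10) and pretreatment as the only factor. The filter left 13815 genes, which held 99.9% of the counts. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are inhibitor over DMSO, and their standard error (SE) is the absolute log2 fold change over the square root of the F statistic. Levels are TMM-scaled CPM, given as mean ± SD over 3 libraries.

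Before the data were examined, 37 gene lists were fixed, covering the response to R848, metabolism, the cell cycle, stress, subunits of the complexes that hold KAT8 and markers of other cell types. The 31 lists with at least 5 tested members were compared with the other genes by camera (limma 3.58.1) with a preset correlation of 0.01, and their p-values were adjusted over these lists. The same lists were tested with an estimated correlation and with fry. A further 7 lists were written after the data had been looked at, and were tested without the members already seen.

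The rule for naming genes was also fixed before the data were examined. It took Kat8, then the 8 largest rises and 8 largest falls among called genes at 5 CPM or more in the higher group whose groups did not overlap, leaving out predicted genes and genes without a symbol. It then took the 2 members with the smallest p from each of the main lists, the 3 that moved with the list from each other called list, the most abundant member of each cell type list and Ifnb1. List members named outside this rule were chosen after their values were seen. Some genes that the rule takes, and the result of one of the later lists, are not reported here.

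Alternatives tried were median-of-ratios size factors, library totals alone, no filter on low counts, a mean of at least 5 CPM, DESeq2 1.42.0, the replicate number as a block, an adjusted p under 0.01, and leaving out each library in turn. Removal of trends with GC content and exon length was added after the data had been seen. Values of single libraries were compared by two-sided exact permutation tests, which cannot go below p = 0.1 with 3 libraries against 3.

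The procedure was tested on simulated data for the comparison of inhibitor with DMSO, using counts drawn for the 13815 tested genes at the depths of these libraries. It recovered 64.2% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 100% of those changed 4-fold. Of 188 genes called, 18 had not been changed. A shifted gene list was called, and 0 of 30 unshifted lists were called by camera. Genes were drawn independently and lists at random, so the effect of correlation between genes on list calls was not tested. Only 67, 67 and 66 genes were changed at these sizes, far fewer than in the data, so the rates need not carry over.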

Results

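RNA sequencing was used to ask how pretreatment with a KAT8 inhibitor alters the transcriptome of R848-stimulated mouse bone marrow-derived macrophages. KAT8, also called MOF, is a lysine acetyltransferase whose best known substrate is histone H4. The data comprised 3 libraries from cells pretreated with DMSO and 3 from cells pretreated with the inhibitor. Total counts were 18441352, 24429778 and 23950178 in the DMSO libraries and 25089320, 24223664 and 23037820 in the inhibitor libraries. Unstimulated cells and cells given the inhibitor without R848 were not among the samples used here, so every difference is one between stimulated cells. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and those of gene lists are from camera.

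With the inhibitor, the cultures had lower mRNA levels of many inflammatory cytokines, chemokines and interferon-stimulated genes, of nearly all tested cholesterol synthesis enzymes and of all tested G2 and M phase genes. Levels of 15 of 20 antioxidant genes were higher. Markers of stromal cells were lower in the same libraries (8 of 9, mean log2 fold change −1.17). Among 13815 tested genes, 3446 were higher and 3667 lower, together 51.5%. At least 2-fold differences were seen for 434 genes that rose and 948 that fell. With only genes at a mean of at least 5 CPM tested, these numbers were 151 and 514. The 3 values of each group did not overlap for 8365 genes (60.6%, against 10% by chance). The groups separated along the leading principal component, which held 71.7% of the variance. Scaling by library totals alone raised the median log2 fold change of all genes by 0.11 and gave 4888 higher and 2842 lower genes. Removal of trends with GC content and exon length gave 4187 higher and 3268 lower. The split between directions is therefore relative to the scaling and to such corrections.

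**Figure D1:**
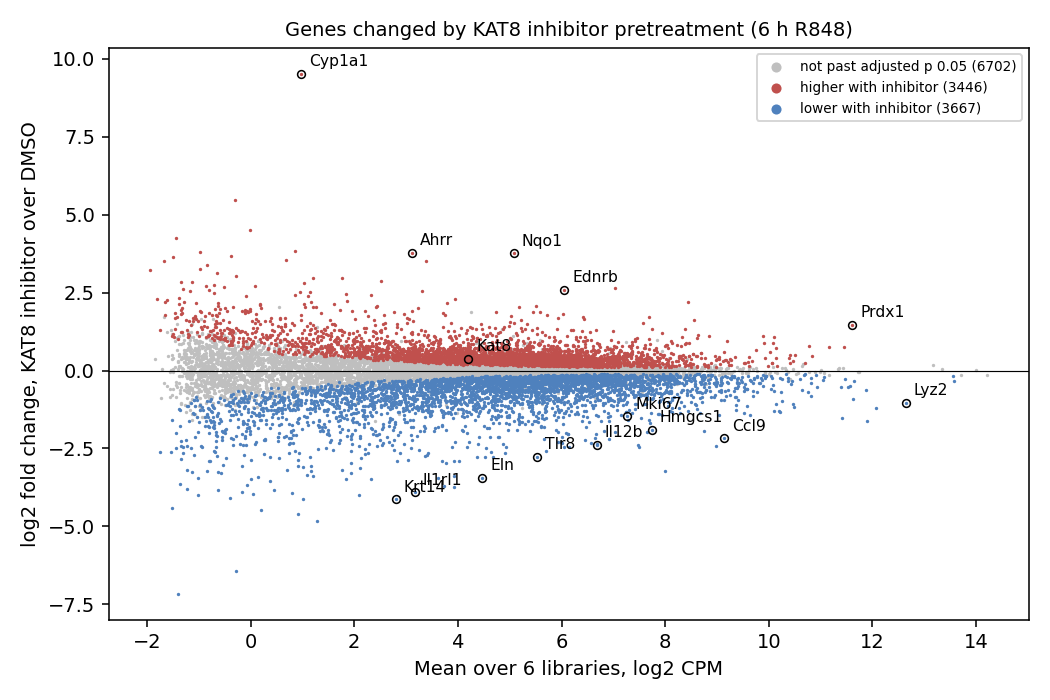
Log2 fold change (KAT8 inhibitor over DMSO, 3 libraries each) against mean expression in log2 CPM, with each point a tested gene. Red points are the 3446 genes that were higher and blue points the 3667 that were lower at adjusted p under 0.05, grey points did not pass, and circles mark labelled genes.

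Kat8 mRNA was measured in every library. Its counts were 280, 391 and 363 with DMSO and 547, 521 and 491 with the inhibitor. The normalised level rose from 16.1 ± 0.727 to 20.8 ± 0.351 CPM (SD, n = 3), a log2 fold change of 0.37 (SE 0.069, adjusted p = 0.00244). The inhibitor acts on the protein, so the mRNA level is not a measure of inhibition. Kat8 (ENSMUSG00000030801) lies on the plus strand of chromosome 7 at 127912516 to 127925837 in mm10, and its exons overlap those of Prss8 on the opposite strand, whose reads cannot be told apart without strand. Of 12 subunits of the MSL and NSL complexes, through which KAT8 is brought to chromatin, 7 rose and 1 (Mcrs1) fell. The counts were the same adjusted over the list alone. The list includes Kat8 itself, which is 1 of the 7 that rose. The median log2 fold change of the 12 was 0.27 (adjusted p = 0.0274, and adjusted p = 0.235 with an estimated correlation). Msl2, a ubiquitin ligase of the MSL complex, rose from 64.9 ± 0.547 to 83.3 ± 0.568 CPM. Ogt, the O-GlcNAc transferase of the NSL complex, rose from 183 ± 9.16 to 242 ± 4.85 CPM. Without DMSO replicate 3 the list no longer passed (adjusted p = 0.0526, range over the settings with the preset correlation 0.0163 to 0.0526). Of 13 other lysine acetyltransferases 4 rose and 3 fell, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.427).

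Among called genes at 5 CPM or more in the higher group, the largest rises were those of Ahrr, the aryl hydrocarbon receptor repressor, and Nqo1, a quinone reductase of the oxidative stress response. Ahrr (ENSMUSG00000021575, chromosome 13, 74211118 to 74292331, minus strand) rose 13.7-fold, from 1.15 ± 0.415 to 16.1 ± 0.77 CPM (SD, n = 3; adjusted p = 2.26e-06). Nqo1 (ENSMUSG00000003849, chromosome 8, 107388225 to 107403206, minus strand) rose 13.5-fold, from 4.65 ± 0.941 to 63.2 ± 2.65 CPM (adjusted p = 4.21e-07). They were followed by the transcription factor Runx3 (log2 fold change 2.96, SE 0.25), Cgref1 (2.86, SE 0.16), the endothelin receptor Ednrb (2.60, SE 0.069), the hyaluronidase Hyal1 (2.55, SE 0.16), the cytokine receptor Il21r (2.45, SE 0.24) and the peptide hormone gene Cck (2.42, SE 0.14). Ednrb was the most abundant of these, at 114 ± 5.93 CPM with the inhibitor. Hyal1 shares exons with Hyal3 and Naa80 on the same strand, and its reads are not fully its own.

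Among the genes that fell, chosen in the same way, the largest changes were those of the keratin gene Krt14, which fell 17.5-fold, and of the vascular addressin Madcam1, which fell 16.0-fold. Krt14 (ENSMUSG00000045545, chromosome 11, 100203162 to 100207548, minus strand) went from 13.2 ± 0.733 to 0.754 ± 0.431 CPM (SD, n = 3; adjusted p = 7.59e-06). Il1rl1, the interleukin-33 receptor, fell from 16.9 ± 1.29 to 1.11 ± 0.183 CPM. Pglyrp2, an amidase that cleaves bacterial peptidoglycan, and the Ets factor Spib fell by 3.73 and 3.71 on the log2 scale. Dpysl5, the smooth muscle gene Cnn1 and elastin (Eln) followed with log2 fold changes of −3.50, −3.48 and −3.45. Elastin is made mainly by stromal and smooth muscle cells, and 8 of 9 stromal markers also fell in these libraries.

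Cytokine mRNAs were mostly lower with the inhibitor. Of 20 tested, 14 fell and 3 rose, with the same counts adjusted over the list alone (median log2 fold change −0.87, adjusted p = 0.000143, and adjusted p = 0.235 with an estimated correlation). Il12b, which encodes the subunit shared by interleukins 12 and 23, fell 5.25-fold, from 173 ± 9.78 to 33.0 ± 1.61 CPM (SD, n = 3; ENSMUSG00000004296, chromosome 11, 44400063 to 44414033, plus strand). Il6 fell 3.25-fold, from 59.8 ± 3.05 to 18.4 ± 1.11 CPM, and Tnf fell by 0.54 on the log2 scale. The 3 that rose were Osm (1.20) and Lif (0.32), members of the interleukin-6 family, and the granulocyte growth factor Csf3 (0.90).

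Of 20 chemokines 12 fell and 3 rose, with the same counts adjusted over the list alone (median −0.63, adjusted p = 0.0229, and adjusted p = 0.368 with an estimated correlation). Ccl9 fell 4.53-fold, from 924 ± 69.2 to 204 ± 16.0 CPM, and Ccl4 fell 2.86-fold, from 276 ± 19.3 to 96.5 ± 2.28 CPM. Cxcl1 (0.48) and Cxcl3 (0.23), which attract neutrophils, and Cxcl14 (0.69) rose. Of 21 effectors of inflammatory macrophages 15 fell and 5 rose, again with the same counts adjusted over the list alone (median −0.58, adjusted p = 0.00312, and adjusted p = 0.235 with an estimated correlation). The scavenger receptor Marco fell 3.54-fold, and the acute-phase gene Saa3 went from 1159 ± 36.9 to 431 ± 14.1 CPM. The 5 that rose were Ptgs2, Slc2a1, Ass1, Cp and Mmp13. In the same libraries 8 of 9 stromal markers were lower with the inhibitor (mean log2 fold change −1.17).

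Interferon-stimulated genes were lower as a group. Of 40 tested, 22 fell, 1 rose and 17 did not pass, with the same counts adjusted over the list alone (median −0.39, adjusted p = 0.000155, and adjusted p = 0.573 with an estimated correlation). The DNA-binding protein gene Ifi205 fell 2.13-fold and the guanylate-binding protein gene Gbp2 fell 1.61-fold, from 670 ± 28.2 to 416 ± 15.5 CPM. The riser was Rsad2, which encodes viperin (0.49). Transcripts of Ifnb1 were at 2, 0 and 2 counts with DMSO and 0, 2 and 0 with the inhibitor, and all 14 interferon-alpha and related genes of the list were at 0, so no difference in type I interferon mRNA was detectable at this depth. As above, 8 of 9 stromal markers were lower in the same libraries.

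The endosomal Toll-like receptor pathway moved in both directions. Of 24 members 7 rose and 6 fell, with the same counts adjusted over the list alone, and the list did not pass (adjusted p = 0.779). The falls included Tlr7, the main receptor for R848 in mice, which went from 141 ± 2.04 to 44.9 ± 16.1 CPM (SD, n = 3; log2 fold change −1.65, SE 0.23). Tlr8 (ENSMUSG00000040522, X chromosome, 167242696 to 167264329, minus strand) fell 6.81-fold, from 80.8 ± 0.996 to 11.9 ± 0.761 CPM (adjusted p = 1.54e-07). The chaperone gene Hsp90b1 fell 1.42-fold, with exons that overlap those of other genes on both strands. Of 24 NF-kB targets and feedback regulators 7 rose and 12 fell, or 8 and 13 adjusted over the list alone, and the list did not pass (adjusted p = 0.179). The adhesion gene Icam1 fell from 850 ± 36.0 to 474 ± 8.92 CPM, while the early response gene Ier3 rose from 114 ± 5.76 to 213 ± 1.05 CPM. Immediate early and AP-1 genes (8 of 19 higher, 7 lower, adjusted p = 0.791) and inflammasome genes (3 of 13 higher, 3 lower, adjusted p = 0.883) did not pass. Adjusted over the list alone, these were 8 and 7, and 3 and 2.

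**Figure D2:**
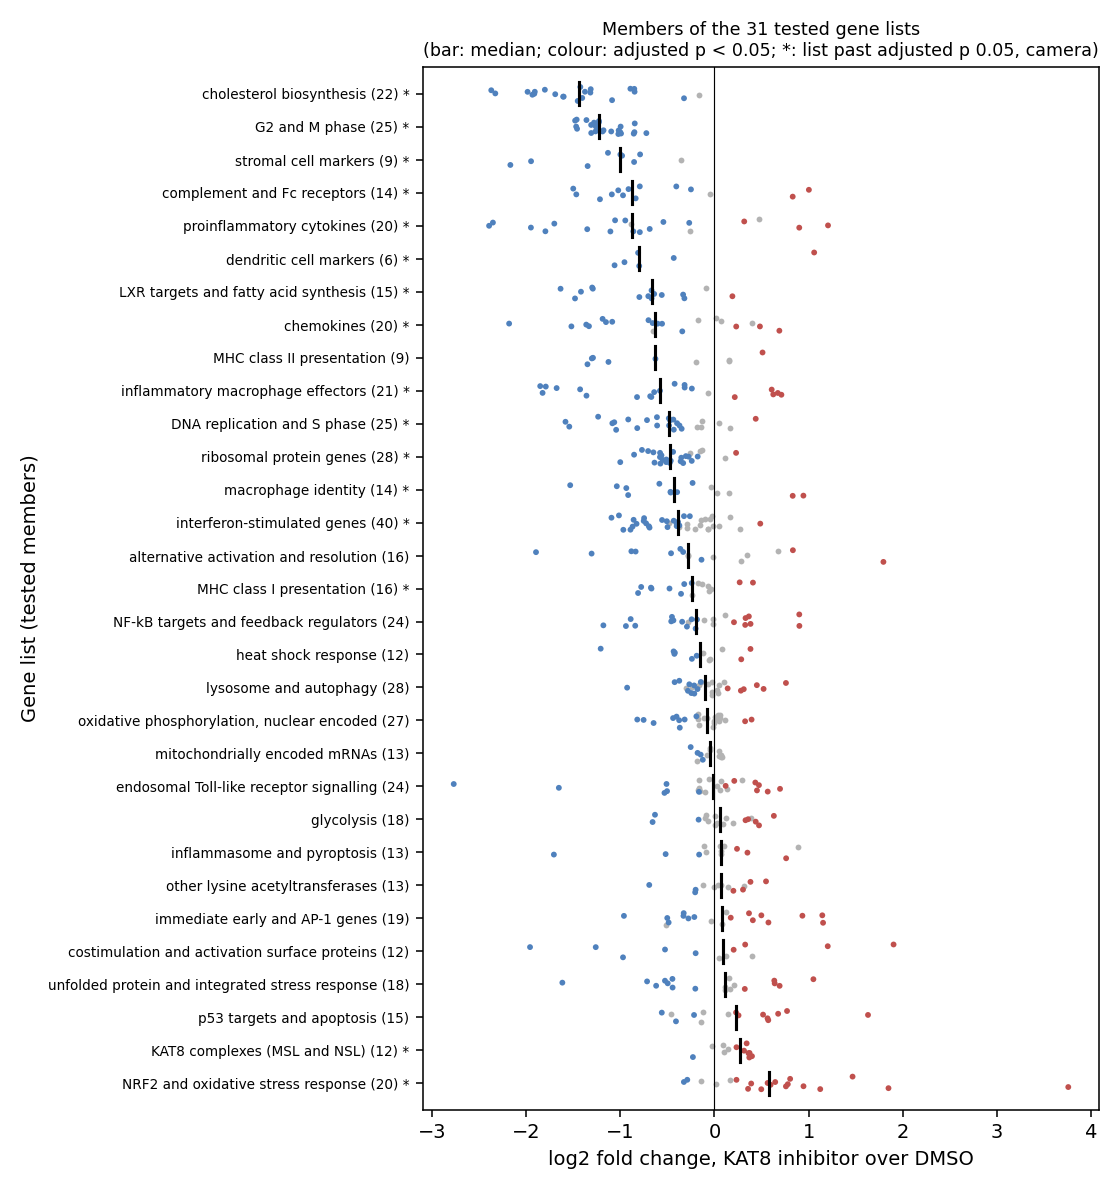
Log2 fold change (KAT8 inhibitor over DMSO) of each tested member of the 31 tested gene lists, with the list's median as a bar. Coloured points passed adjusted p 0.05, and asterisks mark the 16 lists that passed by camera with its preset correlation, 14 lower and 2 higher.

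Of 9 genes for MHC class II presentation 5 fell and 1 (H2-DMa) rose, with the same counts adjusted over the list alone, and the list did not pass (median −0.63, adjusted p = 0.0709). It passed without DMSO replicate 1 (adjusted p = 0.038, range over the settings with the preset correlation 0.038 to 0.129), with library totals (0.0447) and without a filter on low counts (0.0409), but not with an estimated correlation (0.537). Cd74, the invariant chain, fell 2.55-fold, from 67.0 ± 6.12 to 26.3 ± 0.586 CPM (SD, n = 3), and H2-Ab1 fell 2.46-fold. Of 16 class I genes 8 fell and 2 (H2-Q4 and H2-Q6) rose, or 9 and 2 adjusted over the list alone (median −0.24, adjusted p = 0.0237, and adjusted p = 0.470 with an estimated correlation). The immunoproteasome subunits Psmb10 and Psmb8 fell 1.75-fold and 1.71-fold, and Tapbp, whose exons overlap Zbtb22, fell 1.59-fold. The H2-Q genes are near-identical copies of each other, so reads can be shared between them. Stromal markers were lower alongside (8 of 9, mean −1.17).

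Of 12 costimulatory and activation surface proteins 4 rose and 5 fell, or 5 and 5 adjusted over the list alone. Their median was 0.09 and their mean −0.06, and the list did not pass (adjusted p = 0.779). Cd38 fell from 321 ± 9.08 to 82.5 ± 1.32 CPM, and Cd69 fell 2.39-fold. Of 14 complement components and Fc receptors 11 fell and 2 rose, with the same counts adjusted over the list alone (median −0.87, adjusted p = 0.00059, and adjusted p = 0.235 with an estimated correlation). Complement C3 fell from 1527 ± 45.8 to 718 ± 4.72 CPM, C5ar1 fell 2.83-fold and the inhibitory receptor Fcgr2b fell 2.32-fold, while C3ar1 (1.00) and Fcgr3 (0.83) rose. Genes of alternative activation did not pass as a list (2 of 16 higher, 8 lower, or 3 and 8 adjusted over the list alone, adjusted p = 0.223). Mrc1, the mannose receptor, fell from 159 ± 2.55 to 86.5 ± 1.13 CPM, and Il4ra rose from 215 ± 2.85 to 383 ± 14.0 CPM. Stromal markers (8 of 9 lower, mean log2 fold change −1.17) fell alongside these groups.

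Cholesterol synthesis was the list with the smallest p. Of 22 genes 21 fell and Ebp did not pass, and 22 fell adjusted over the list alone (median −1.44, adjusted p = 1.56e-12, and adjusted p = 0.235 with an estimated correlation). Hmgcs1, which makes the HMG-CoA used by the rate-limiting reductase of the pathway, fell 3.75-fold, from 338 ± 9.06 to 90.0 ± 2.34 CPM (SD, n = 3; ENSMUSG00000093930, chromosome 13, 119690379 to 119708260, plus strand). Hsd17b7 and Cyp51, enzymes of later steps, fell 3.76-fold and 3.23-fold, and exons of Cyp51 overlap those of Akap9 on the opposite strand. Of 15 liver X receptor targets and fatty acid synthesis genes 13 fell and 1 (Mylip) rose, with the same counts adjusted over the list alone (median −0.67, adjusted p = 5.71e-06, and adjusted p = 0.235 with an estimated correlation). Fads2, Scd2 and Fasn, which desaturate or synthesise fatty acids, fell 3.10-fold, 2.67-fold and 2.45-fold. Lists for glycolysis (5 of 18 higher, 3 lower, adjusted p = 0.52), nuclear-encoded oxidative phosphorylation (2 of 27 higher, 9 lower, adjusted p = 0.223) and lysosome and autophagy (6 of 28 higher, 10 lower, adjusted p = 0.48) did not pass, with the same counts adjusted over the list alone. Of 13 mitochondrially encoded mRNAs 4 fell and 9 did not pass, with 2 lower adjusted over the list alone (adjusted p = 0.48). Without DMSO replicate 1, oxidative phosphorylation passed (adjusted p = 0.0433, range over the settings with the preset correlation 0.0433 to 0.512), but it did not with an estimated correlation (0.864). The stromal markers moved with the lipid lists as well, 8 of 9 being lower.

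Proliferation genes were lower with the inhibitor. All 25 tested G2 and M phase genes fell, also when adjusted over the list alone (median −1.23, adjusted p = 9.45e-12, and adjusted p = 0.235 with an estimated correlation). Mki67, which encodes the Ki-67 proliferation antigen, fell 2.77-fold, from 226 ± 14.0 to 81.8 ± 6.16 CPM (SD, n = 3; ENSMUSG00000031004, chromosome 7, 135689784 to 135716361, minus strand). Ccna2, cyclin A, fell 2.28-fold. Of 25 S phase genes 19 fell and 1 (E2f1) rose, or 19 and 2 adjusted over the list alone (median −0.48, adjusted p = 1.7e-05, and adjusted p = 0.235 with an estimated correlation). Uhrf1, a cofactor of maintenance DNA methylation, fell 2.91-fold and the ribonucleotide reductase subunit Rrm1 fell 2.06-fold. Among 15 p53 targets and apoptosis genes 8 rose and 3 fell, or 8 and 4 adjusted over the list alone, and the list did not pass (adjusted p = 0.179). The cell cycle inhibitor Cdkn1a rose from 183 ± 14.2 to 565 ± 12.5 CPM. The cell cycle lists fell together with 8 of 9 stromal markers.

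Antioxidant genes controlled by NRF2 rose. Of 20 tested, 15 rose and 2 (the metallothioneins Mt1 and Mt2) fell, with the same counts adjusted over the list alone (median 0.58, adjusted p = 0.000123, and adjusted p = 0.323 with an estimated correlation). Besides Nqo1, the peroxiredoxin Prdx1 rose from 1663 ± 92.3 to 4591 ± 139 CPM (SD, n = 3) and the sulfiredoxin Srxn1 from 594 ± 44.1 to 1294 ± 47.0 CPM. The heat shock list (2 of 12 higher, 6 lower, adjusted p = 0.179) did not pass, with the same counts adjusted over the list alone. For the unfolded protein and integrated stress response, 5 of 18 genes rose and 8 fell, or 6 and 8 adjusted over the list alone (adjusted p = 0.859), with a median of 0.11 and a mean of −0.05. Stromal markers moved the other way from the antioxidant genes (8 of 9 lower, mean −1.17).

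Of 28 ribosomal protein genes 23 fell and 1 (Rpl3) rose, or 24 and 1 adjusted over the list alone (median −0.47, adjusted p = 5.71e-06, and adjusted p = 0.368 with an estimated correlation). Rpl6 went from 372 ± 37.0 to 206 ± 7.96 CPM and Rps18, which overlaps Vps52, from 74.3 ± 1.20 to 47.4 ± 1.04 CPM (SD, n = 3). These genes have many processed pseudogenes, and how shared reads were counted is not known. Stromal markers were lower in the same libraries (8 of 9).

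**Figure D3:**
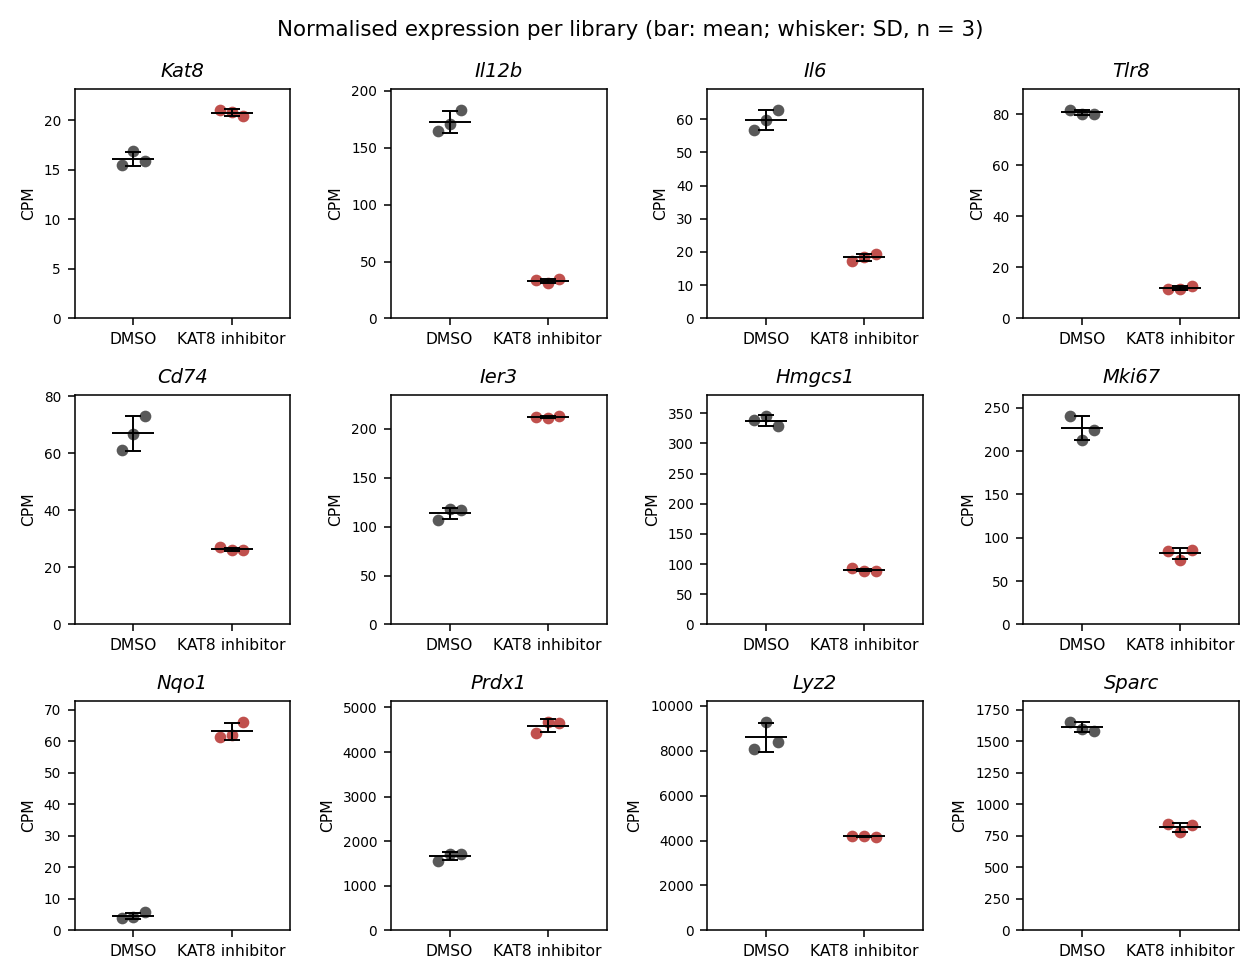
TMM-scaled expression in CPM of 12 genes in each of the 3 DMSO and 3 KAT8 inhibitor libraries, with the mean as a bar and the SD as whiskers. Each vertical axis starts at 0, and the values of the groups do not overlap for any gene shown.

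Of 14 macrophage identity genes 9 fell and 2 (Cd300a and Fcgr3) rose, with the same counts adjusted over the list alone (median −0.43, adjusted p = 0.0484, and adjusted p = 0.482 with an estimated correlation). Lyz2, lysozyme, fell from 8596 ± 632 to 4190.0 ± 37.1 CPM (SD, n = 3), while Csf1r, the M-CSF receptor, had a log2 fold change of −0.03 that did not pass. The list no longer passed without DMSO replicate 2 (adjusted p = 0.0865), DMSO replicate 3 (0.0636), inhibitor replicate 1 (0.0553) or inhibitor replicate 3 (0.0618), with the replicate number as a block (0.0564), or with a mean of at least 5 CPM (0.052), over a range of 0.0226 to 0.0865 under the settings with the preset correlation.

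Transcripts of stromal cells were abundant. Of 9 tested markers 8 fell and Lum did not pass, and 9 fell adjusted over the list alone (mean log2 fold change −1.17, adjusted p = 2.33e-05, and adjusted p = 0.235 with an estimated correlation). Sparc, a matrix protein, fell from 1612 ± 38.1 to 817 ± 34.6 CPM (SD, n = 3), and the collagen gene Col1a2 from 1701 ± 115 to 669 ± 20.2 CPM. Of 6 dendritic cell markers 5 fell and 1 (Batf3) rose, with the same counts adjusted over the list alone (median −0.80, adjusted p = 0.0415, and adjusted p = 0.235 with an estimated correlation). Bst2, the most abundant of them, is also an interferon-stimulated gene and fell from 125 ± 4.84 to 92.3 ± 4.71 CPM. The dendritic list did not pass without DMSO replicate 2 (adjusted p = 0.0524) or with the replicate number as a block (0.0564), and without a filter on low counts its median turned to 0.10 (adjusted p = 0.294, range over the settings with the preset correlation 0.0204 to 0.294). Other cell types had too few detected markers for a list test. S100a8, a neutrophil gene, fell from 5.55 ± 0.394 to 2.10 ± 0.344 CPM, and the mast cell gene Kit from 1.56 ± 0.239 to 0.503 ± 0.21 CPM. Pf4, a megakaryocyte gene that macrophages also express, fell from 15.7 ± 1.87 to 11.9 ± 0.792 CPM (adjusted p = 0.0139) but did not pass without inhibitor replicate 3 (adjusted p = 0.0517, range 0.00542 to 0.0517). Of the neutrophil markers 3 were tested (2 fell and 1 rose), of the B cell markers 2 (neither passed), of the erythroid and megakaryocyte markers 2 (1 fell), of the mast cell markers 1 (it fell), and of the T and NK cell markers 0. Adjusted over the list alone, these counts were the same.

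Of the 31 tested lists, 16 passed with the preset correlation of camera and 0 with an estimated correlation (4 at an unadjusted p under 0.05). By fry 24 passed, a test of whether a list's genes move on balance in a single direction, without comparison with the other genes. Libraries of the groups also differed slightly in makeup. Detected genes numbered 16946 ± 165 with DMSO and 17206 ± 62.9 with the inhibitor. Mitochondrial transcripts held 2.52% ± 0.0724 and 2.70% ± 0.0563 of counts, and TMM factors were 0.963 ± 0.017 and 1.04 ± 0.00691 (SD, n = 3). Each of these measures had an exact permutation p of 0.1, the smallest possible here. The mitochondrial share is of library totals, so it is not directly comparable with the TMM-scaled falls of mitochondrially encoded mRNAs given above.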

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

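The removal of GC content and length trends was chosen after the data were seen, and the other alternatives before. Of the 66 named genes, 65 kept their direction and call under every setting in which they were tested. Most had been picked from these data for large changes or small p-values, which made this likely. Of the 31 tested lists, 6 kept their call under every setting, the other set tests included. All 6 were lists that did not pass, since each of the 16 that passed lost its call with an estimated correlation. Of all called genes, 82.1% to 99.4% were also called by each other fit, all in the same direction. No call was reversed, though without a filter on low counts the median of the dendritic list turned to 0.10. With a mean of at least 5 CPM, 10470 genes were tested. Of these 151 were at least 2-fold higher and 514 at least 2-fold lower, against 434 and 948 in the main fit. All higher and lower genes, at 2904 and 3006, declined by a smaller share. Many of the 2-fold differences therefore lay in genes with a lower mean. At an adjusted p under 0.01, 2257 genes were higher. With an estimated correlation 0 lists passed (4 at an unadjusted p under 0.05), and why every call ended was not tested. By fry 24 passed. Unlike camera, fry does not compare a list with the other genes, so its count answers a different question. DESeq2 called 3038 genes higher and 3455 lower. With GC and length trends removed, 4187 were higher and 3268 lower, so the balance of directions turned. Leaving out each library in turn gave 2851 to 3269 higher genes, 3230 to 3611 lower genes and 14 to 18 lists. With a mean of at least 5 CPM macrophage identity did not pass, and without a filter the dendritic list did not. The list calls that leaving out a library ended were macrophage identity, dendritic cell markers and KAT8 complexes. With the replicate block 3215 genes were higher, 3510 lower and 14 lists passed, macrophage identity and dendritic cell markers being lost. Same-numbered libraries shared no deviation (r = −0.034, −0.003 and 0.024 across genes, which are not independent), and 2 of 6 libraries correlated best with their own number, so the numbers were not taken as pairs. Small changes can be missed at this depth, since 64.2% of 1.5-fold changes were recovered in a simulation with far fewer changed genes.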

Other observations

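Some lists in these paragraphs were written after the data had been looked at. Those of stromal markers, ribosomal protein genes, cytokines, chemokines, NF-kB targets and macrophage identity genes had been fixed before. Among the tests below, some were chosen only after the result was seen. These were the tests of contractile genes against stromal markers, library totals for ribosomal protein mRNAs, risers among inflammatory genes, macrophage identity genes and Xist. The p-values of the 7 later lists are for members not seen when the lists were written, adjusted together. Contractile genes fell: of 18 tested, 17 were lower and Srf did not pass. Acta2, Myl9 and Cnn1 had been seen before the list was written, and without them 14 of 15 were lower (median log2 fold change −1.02, camera adjusted p = 7.27e-08, and adjusted p = 0.180 with an estimated correlation). Tagln, which had not, fell by 2.45 on the log2 scale, Mylk by 2.07 and Actg2 by 4.82.

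Innate receptors were also lower. Of 21 pattern recognition receptors 14 fell and 3 (Tlr4, Tlr9 and Ly96) rose. Several, such as Tlr7 and Tlr8, had already been seen. Of the 14 that had not, 9 fell and 2 rose (median −0.56, adjusted p = 0.00968, and adjusted p = 0.213 with an estimated correlation), the falls including the formyl peptide receptor Fpr1 at −2.28 and the C-type lectin Clec4e at −1.29. Of 9 interleukin-1 family receptors and their inhibitors 4 fell and 2 rose. The falls included Il1rl1 (−3.91), Il18r1 (−2.80) and Il18rap (−2.65), neighbours on chromosome 1 that had prompted the list, and the 5 members not yet seen did not pass (adjusted p = 0.876). Ribosome biogenesis genes did not pass (3 of 16 higher, 4 lower, adjusted p = 0.772).

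Stromal markers fell by different amounts. Fewer stromal cells of a single uniform kind would lower their transcripts by about a common factor. The log2 fold changes of the 9 markers, however, spanned 1.81. Those of the 5 at 100 CPM or more with DMSO spanned 1.16, from −1.95 for Col3a1 to −0.79 for Dcn. A uniform loss of stromal cells alone therefore would not give these values. An uneven loss among kinds of stromal cells was not tested and stays open. So does a smaller number of such cells together with a change in their transcripts, or expression of these genes by the macrophages. The median of the 15 contractile genes not seen before differed from that of the stromal markers by −0.0225, but these genes ranged from −4.82 for Actg2 to −0.04 for Srf, so the medians do not decide whether they fell with stromal cells. The labels name no sort of the cells, and collagen transcripts summed to 3850, 3164 and 3265 CPM with DMSO and 1355, 1274 and 1339 CPM with the inhibitor.

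Ribosomal protein mRNAs were lower by a median of −0.47. Genes matched on exon length and abundance had a median of −0.0896, and 3 of 10000 matched lists lay as low. Exon length joined all annotated exons of a gene, with a median of 1918.5 bases for the ribosomal protein genes. The length of the expressed transcripts was therefore not matched. Matched genes were drawn independently, so the share of lists takes no account of correlation among the ribosomal protein genes. The summed TMM-scaled CPM of 21 pseudogenes named after their ribosomal protein parents fell with them (log2 ratio −0.44). A shift of shared reads to these 21 would have raised the sum. Pseudogenes under other names were not included, so a shift of reads to those was not tested. Scaling by library totals raised the median of all genes by 0.11 and left that of the ribosomal protein genes at −0.36. The list still passed by camera (adjusted p = 1.49e-06). That test compares a list with the other genes, so a shift of all genes could hardly change its call. A change in the cells stays a hypothesis, since the counting of reads that match several places is not known. The call also ended with an estimated correlation (camera adjusted p = 0.368).

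The lower cytokines and chemokines were weighed against a uniformly weaker response to R848 and a smaller share of macrophages. Of 64 tested cytokine, chemokine and NF-kB list members 13 rose, 7 of them on the NF-kB list, which itself did not pass. Among all 13815 tested genes 3446 rose, so the risers show only that not every member fell. A weaker response to R848 together with other changes stays open. Macrophage identity genes spanned 2.47 log2 units, from −1.53 for Mpeg1 to 0.94 for Cd300a, which a smaller share of macrophages alone would not give. A smaller share together with changed expression of these genes stays open. Gene-specific effects of the inhibitor stay open, as does a loss of signal through the lower Tlr7, and without unstimulated cells an effect on the response cannot be separated from an effect on the starting state.

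A hypothesis drawn from Ahrr and Nqo1 was that targets of the aryl hydrocarbon receptor rose, and 4 of the 6 other tested targets did: Cyp1a1, Cyp1b1, Tiparp and Xdh. Without Ahrr and Nqo1, which had prompted it, the list passed (adjusted p = 0.0143, and adjusted p = 0.180 with an estimated correlation). Cyp1a1 was at 0 counts in all 3 DMSO libraries and at 115, 88 and 94 counts with the inhibitor (3.95 ± 0.459 CPM, SD, n = 3), at least 84.5-fold higher against a limit of 3 counts over the DMSO group. The compound itself may act on this receptor, which these data do not test. A hypothesis drawn from Snhg6 was that host genes of small nucleolar RNAs rose as a class by at least 0.5. It was not borne out, since the 12 other host genes had a median of 0.26, although 6 of the 12 rose and 1 fell (adjusted p = 0.0268, and adjusted p = 0.366 with an estimated correlation).

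KAT8 is part of the MSL complex, which in flies acts on the X chromosome, so X-linked genes were compared with autosomal genes. The median log2 fold change of 457 X-linked genes minus that of 13291 autosomal genes was −0.11 (permutation p over genes, which are not independent replicates, of 1e-04, the smallest that 10000 permutations give). The X chromosome had the lowest median of 20 chromosomes. Among X-linked genes 14.7% rose and 32.2% fell, against 25.3% and 26.4% of autosomal genes. Of 7 tested Y-linked genes 3 rose, Ddx3y (0.52), Uty (0.55) and Eif2s3y (0.30), and Mid1-ps1 fell (−1.23). The difference was −0.0868 among genes at 20 CPM or more and −0.12 with GC and length trends removed. It ranged from −0.13 to −0.0993 when each library was left out. Across 9 other splits of the libraries, which mix the treatments, it was at most 0.0578 in size. Both −0.0868 and −0.0993 fell short of the smallest X-linked difference that had been set beforehand to count. The difference is small, was found in stimulated cells only, and may stem from which genes lie on the X chromosome. A different mix of male and female cells would bring Xist, which was at most 0.0862 CPM in any of the 6 libraries, so it does not account for the shift.

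The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. The real split gave 7113 changed genes, and the highest other 1, so 1 of 10 splits gave as many. For gene lists, 2 of 10 splits gave as many as the real 16, because the split of DMSO replicate 1 with inhibitor replicates 1 and 2 against the rest also gave 16. Each of the other splits has libraries of both treatments on each side, so they are no reference without an effect.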
